A study of Mus musculus with 6 samples.

How the data were processed

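RNA was measured in 6 libraries of the mouse ovarian cancer line ID8, 3 labelled WT and 3 labelled KO. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was selected with poly-T beads, and fragmented RNA was copied with random hexamers before ligation of adapters and amplification. Per the submitters' processing notes, the tools were fastp, HISAT2 2.0.5 and featureCounts 1.5.0-p3, with the mouse genome build mm10. Their settings, the strand mode, the annotation release and any removal of duplicate reads are not given in the sources used here. The deposited values are raw counts of reads per gene, with 1 column per library and no normalization by the authors. Columns numbered 1 to 3 in each group were matched to the replicates titled 4 to 6 through the labels, and no columns of other samples were present.

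The table lists 53465 Ensembl mouse genes, of which 53274 were matched to a symbol and to coordinates in the GENCODE M21 annotation of the same build. A total of 12794 genes had a count in at least 1 library and 5581 in all 6. Total counts ranged from 1687466 to 3126208 per library, so that 1 count was worth 0.593 CPM in the smallest library and 0.320 CPM in the largest. Intervals are at 95%, and a group without counts was set at a floor of 3 counts over the group.

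Genes were tested with edgeR 4.0.16 in R 4.3.3. Low genes were removed with filterByExpr (minimum count 10), which left 8200, libraries were scaled with TMM, and a quasi-likelihood model with robust estimation was fitted with the group as its only term. The test was two-sided with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. CPM values use the TMM-scaled library sizes. Gene lists were written before the data were examined, 29 in all, and the 26 with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Counts adjusted over a list alone use the same gene p-values.

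The genes named were fixed by a rule. It took Nat10 and 8 genes tied to the study's title or question, and the 10 largest rises and 10 largest falls past the threshold with an average log2 CPM of at least 2, groups that do not overlap and a proper gene name. It also took up to 4 genes with the smallest adjusted p from each list called by camera and from the 5 DNA damage lists. Col6a1, Col1a1, Upk1b, Krt8, Ddit4, Asns, Atf4, Ptgs2, Esam, Dcn, Msln, Anxa1, Aebp1, Olfml2b, Krt19, Aldh2, Tspan8 and Gm42418 fall outside this rule and were named after their values were seen, as were the YAP targets. Some genes the rule took and some results are not reported here.

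Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library totals, no filter on low counts, a stricter filter (1 CPM in 3 libraries), the replicate number as a block, a threshold of 0.01, a test against a log2 fold change of 1, a prior count of 0.5, camera with an estimated correlation, directional fry, mixed fry (a test for changes in either direction), cameraPR on the DESeq2 statistic, and leaving out each library. Chosen after seeing the data were a filter for counts in all 6 libraries, removal of ribosomal RNA genes, thinning every library to 1687466 counts, division of each library's counts by the count at which its histogram peaks, the NRF2 list without Txn1, and a correction of log2 CPM for GC content and exon length by loess (span 0.5).

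The scripts were tested on simulated counts drawn from these libraries' means, sizes and spread for the KO against WT comparison, with 200 of 8200 genes changed in each of 10 simulations. The edgeR test recovered 1.35% of genes changed 2-fold, 23.5% of those changed 4-fold and 42.1% of those changed 8-fold, and 6% of its calls were false. Among genes of at least 200 CPM it recovered 4.17%, 86.5% and 100% at the same sizes. The unfolded protein response list, shifted by -0.70 on the log2 scale, was called in 10 of 10 simulations by camera with the preset correlation. With an estimated correlation it was called in 0 of 10, and none of 250 unshifted lists was called. No other list and no smaller shift was simulated, so power for those is not known. Genes were simulated independently of each other, so false calls of lists with correlated members were not tested. In the data the estimated correlation of the called lists ran from -0.036 for MHC class I antigen presentation to 0.137 for p53 target genes. It lay under the preset 0.01 for the MHC, NRF2, mitosis, histone and TGF-beta lists.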

Results

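Gene expression was measured by RNA sequencing in ID8 cells, a mouse ovarian surface epithelial line that forms ovarian tumours in mice. The study asked which transcripts change when NAT10 is depleted. NAT10 is the enzyme that places N4-acetylcytidine (ac4C) on RNA, and the stated interest was the DNA damage response. The libraries fall into 2 groups of 3, labelled WT and KO. The series describes a control guide line and a line carrying a guide against Nat10, and WT was taken as the former and KO as the latter. Guide and line are thus confounded, so any other difference between the lines cannot be told apart from an effect of the guide. The labels number the replicates 4 to 6 in each group and do not say whether they are separate cultures, so p-values measure only the spread between these libraries, which may be technical. Total counts were 1687466, 2148715 and 1811225 in the WT libraries and 2541273, 2234305 and 3126208 in the KO-labelled libraries. The KO-labelled totals averaged 2633900 ± 453110 against 1882500 ± 238740 (SD, n = 3 per group; exact permutation test, two-sided p = 0.1, the smallest p that 3 against 3 libraries allow).

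Nat10 mRNA, the product of the targeted gene, was not lower in the libraries labelled KO. Its counts were 168, 128 and 292 in WT replicates 4, 5 and 6, and 315, 133 and 445 in KO replicates 4, 5 and 6. Scaled for depth, Nat10 stood at 112 ± 53.1 CPM (counts scaled by library size) in WT and 106 ± 43.1 in KO-labelled libraries (SD, n = 3 per group). The log2 fold change was -0.07 ± 0.48 (SE), with a 95% interval from -1.09 to 0.94 and an adjusted p of 0.99996 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Its sign turned under 4 of the other settings run on all libraries and without WT replicate 6 or KO replicate 5. Nat10 (ENSMUSG00000027185) lies on chromosome 2 from 103721256 to 103761270 in mm10, and its counts cover exons as a whole, so an edit that leaves the transcript in place would not lower them. Directions below are therefore those of libraries labelled KO against libraries labelled WT, not of cells shown here to have less Nat10 mRNA. Thumpd1, which encodes a partner protein of NAT10 in tRNA acetylation, stood at 13.98 ± 19.1 CPM in WT and 53.05 ± 45.3 CPM in KO-labelled libraries (SD, n = 3 per group; edgeR adjusted p = 0.99996).

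The genes that rose in the KO-labelled libraries included several of secreted and membrane proteins. This class was not tested, and such genes also stand among the falls, Pltp and C3 among them. Ankrd1, a muscle and stress-responsive nuclear protein, rose 6.57-fold, from 217 ± 47.9 to 1426 ± 179 CPM (SD, n = 3 per group). Adamts1, a secreted metalloprotease, rose 5.89-fold from 82.8 ± 14.5 to 488 ± 112 CPM. Grem1, a secreted antagonist of bone morphogenetic proteins, had no count in any WT library and 206, 167 and 112 counts in KO-labelled libraries. This was 111-fold higher when WT is set at 3 counts over the group, a floor that covers counting error only. The bone morphogenetic protein modulator Bmper rose 3.60-fold and the dynein heavy chain Dync1h1 3.64-fold, the last at 2009.5 ± 1258 CPM with its highest value in KO replicate 6. Without that library the log2 fold change of Dync1h1 went from 1.86 to 1.24. Gpnmb, a membrane glycoprotein, rose 3.80-fold, Plxdc2 3.57-fold and C1s1, a complement serine protease, 3.03-fold.

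The genes that fell included enzymes of lipid, sugar and thiol metabolism. Tgm2, the tissue transglutaminase that crosslinks proteins, went from 250 ± 8.19 to 1.66 ± 1.72 CPM (SD, n = 3 per group), a log2 fold change of -7.22 ± 0.65 (SE), or -8.11 to -6.66 with 1 library left out. Pltp, the phospholipid transfer protein, had 87, 152 and 133 counts in WT and 1 count over the KO-labelled group, a ratio of 557 with a 95% counting interval of 99.98 to 22002. Cyp2j6, a cytochrome P450, had 3 counts over the KO-labelled group against 117, 121 and 138 in WT, a ratio of 190.8 with an interval of 65.3 to 925. These intervals and the floor of 3 counts cover counting error only, because reads copied by amplification are not independent molecules. Gfpt2, an enzyme of hexosamine synthesis, fell 12.6-fold with 110, 4 and 57 counts in KO-labelled libraries, a log2 fold change of -3.66 that became -4.70 without KO replicate 4. The phosphoglucomutase Pgm1 fell 5.68-fold from 455 ± 110 to 80.0 ± 8.22 CPM and thioredoxin Txn1 3.54-fold from 815 ± 116 to 230 ± 22.1 CPM. Keratin 18 (Krt18) fell 3.33-fold, the cytokine receptor kinase Jak1 3.28-fold and complement C3 2.85-fold. Txn1, Cyp2j6, Pgm1 and Jak1 all lie on chromosome 4. Txn1 starts at 57943373, and Cyp2j6, Pgm1 and Jak1 start at 96516138, 99929414 and 101152367. A change of these regions in place of a change of single genes or pathways is not excluded.

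**Figure D1:**
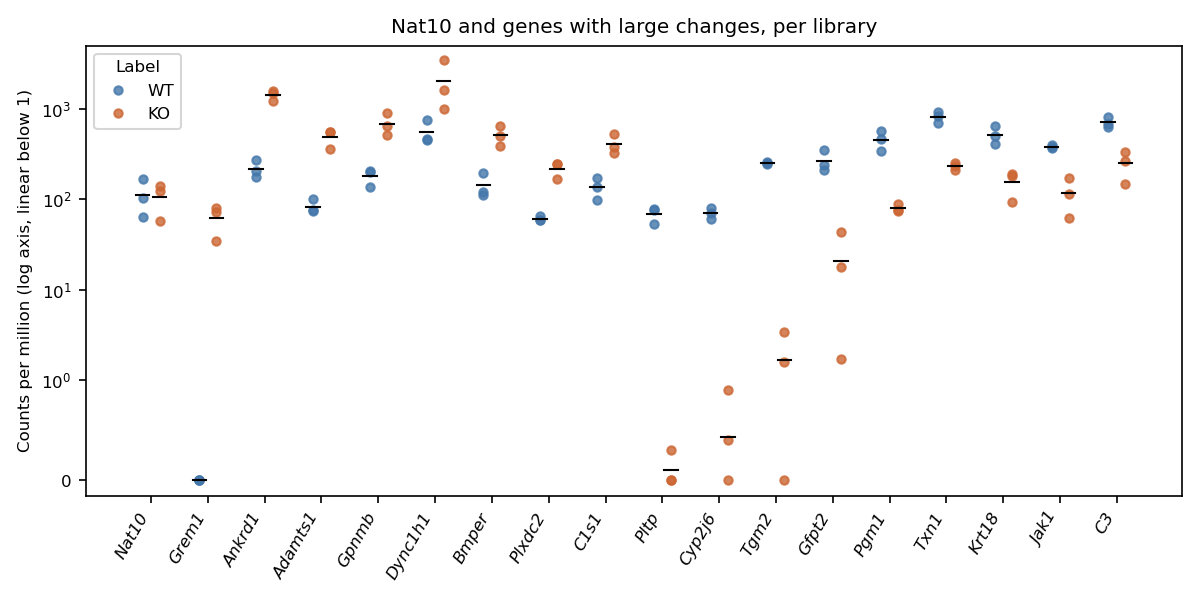
CPM of Nat10 and of genes with large rises and falls taken by the fixed rule, with 1 point per library (3 WT, 3 labelled KO) and a bar at each group mean, on an axis that is logarithmic above 1 and linear below. The groups overlap for Nat10 (means 112 and 106) and do not overlap for the other genes.

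In all, 33 of 8200 tested genes passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, 15 higher and 18 lower in KO-labelled libraries, and 28 of them differed at least 2-fold (14 higher, 14 lower). No gene among the 33 had overlapping groups, and 532 genes had an unadjusted p under 0.05, where 410 would be the chance number. Among all tested genes 14.9% had groups that did not overlap, where chance gives 10%. Beyond the genes above, the mesothelial antigen Msln (1.05 ± 0.17, log2 fold change and SE), Anxa1, Aebp1, Olfml2b and B2m were higher. Krt19, Hspa5, Hsp90b1, Hyou1, Gsta4, Aldh2, Tspan8 and Gm42418 were lower. The reads of Gm42418 overlap ribosomal RNA, and its share of counts was 9.72% ± 0.389 in KO-labelled against 12.9% ± 0.858 in WT libraries (SD, n = 3 per group; exact permutation p = 0.1). The genes called were mostly abundant, with a median of 477 CPM against 36.6 CPM for all tested genes, and 26 of the 33 lay in the most abundant decile.

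Fewer genes were called with 1 library left out. The count was 6 without WT replicate 5, 6 without WT replicate 6, 15 without KO replicate 4, 20 without KO replicate 5 and 18 without KO replicate 6, and 29 without WT replicate 4. Ankrd1, Adamts1, Tgm2, Pgm1 and Txn1 were the 5 genes called whichever library was left out, with edgeR adjusted p-values of at most 0.00211, 0.0177, 0.00745, 0.0189 and 0.0189. The other 28 genes lost their call in at least 1 of these fits. Log2 fold changes moved in some, from 1.24 to 2.20 for Dync1h1 and from -4.70 to -3.12 for Gfpt2, and little in others. Hsp90b1, Aebp1, C1s1, Hyou1 and Plxdc2 were called in none of these fits. Log2 fold changes ran from -0.85 to -0.79 for Hsp90b1 and from 1.09 to 1.16 for Aebp1. They ran from 1.39 to 1.801 for C1s1, from -1.36 to -1.11 for Hyou1 and from 1.74 to 2.004 for Plxdc2. Whether the smaller sample or the library left out ended these calls was not tested. DESeq2 called 234 genes, 106 higher and 128 lower, and these included all 33. limma-voom called 43, and the genes it did not call included Tgm2 (adjusted p = 0.0976), Grem1 (0.156), Pltp (0.0976), Cyp2j6 (0.165), Gfpt2 (0.131) and Plxdc2 (0.0856). With library totals in place of TMM 43 genes passed, 27 higher and 16 lower, and with only genes counted in all 6 libraries 36 passed, 21 higher and 15 lower. Annotated exons of other genes overlap 19.3% of the exons of Pltp, 18.4% of C1s1, 13.7% of Tgm2 and 13.6% of Pgm1. Among genes described further below, the share was 23.2% for Ccn2, 19.1% for Gadd45a, 18.3% for Fdft1, 13.6% for G6pdx, 10.3% for Hsp90b1 and 10.2% for H2afx. The strand setting of the counting is not given in the sources used here, so part of the reads of these genes cannot be assigned with certainty.

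The genes of DNA repair and damage signalling, the subject of the study's question, were not called as groups by camera. None of 31 tested genes of homologous recombination and the Fanconi pathway, 18 of end joining and break signalling, 31 of excision and mismatch repair or 26 of damage checkpoint signalling passed in edgeR, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 these lists held 0, 1, 1 and 2 genes, all lower, and DESeq2 called 0, 0, 1 and 1. Camera gave adjusted p-values of 0.248, 0.304, 0.248 and 0.277, with median log2 fold changes of -0.19, -0.32, -0.17 and -0.23. The smallest p-values in each list belonged to H2afx, the histone H2AX phosphorylated at breaks (149.8 ± 65.0 to 44.4 ± 11.9 CPM, edgeR adjusted p = 0.245, DESeq2 0.00796), and Rad23b of nucleotide excision repair (674 ± 126 to 326 ± 147 CPM, edgeR 0.329, DESeq2 0.0268), with n = 3 per group. They also belonged to Xrcc5, the Ku80 subunit (71.2 ± 10.5 to 26.2 ± 2.47 CPM, edgeR adjusted p = 0.689), and Rad50 (253 ± 66.1 to 161 ± 26.1 CPM, edgeR adjusted p = 0.776). Directional fry did call excision and mismatch repair lower, with an adjusted p of 0.0181. Mixed fry, which tests for changes in either direction, gave adjusted p-values of 0.441, 0.0735, 0.00599 and 0.0121 for these lists in the order first given. It also passed lists that camera did not call, such as ribosome biogenesis (0.00922). In simulations the edgeR test recovered 1.35% of genes changed 2-fold, so changes of that size in single genes are not excluded. Shifts of these lists were not simulated. Rad23b starts at 55350043 and Txn1 at 57943373 on chromosome 4, so a change of that region in place of a change of their pathways is not excluded.

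The p53 target genes stood higher as a group in camera with the preset correlation. Of 26 tested members, 21 had an estimate above 0 and none passed in edgeR, over all genes or adjusted over the list alone, while 5 had an unadjusted p under 0.05 (4 higher, 1 lower) and DESeq2 called 3, all higher. The median log2 fold change was 0.71, and camera gave an adjusted p of 4.7e-04, against an adjusted p of 0.265 with an estimated correlation and 0.247 in directional fry. Cdkn1a, the cyclin-dependent kinase inhibitor p21, went from 31.3 ± 21.3 to 135.5 ± 16.9 CPM (SD, n = 3 per group; edgeR adjusted p = 0.297, DESeq2 0.00906). Plk2 went from 279 ± 97.1 to 544 ± 117 CPM, Mdm2, the ligase that degrades p53, from 65.2 ± 23.7 to 140.1 ± 26.1 CPM, and Gadd45a from 0.692 ± 0.756 to 37.0 ± 23.9 CPM. Each of these 4 genes was higher in every KO-labelled library than in any WT library, but they were taken for their small p-values. Over the 26 members, 6 were higher and 1 lower without overlap of the groups, against 14.9% of all tested genes in either direction. Trp53 itself stood at 115 ± 43.7 and 126 ± 14.3 CPM (edgeR adjusted p = 0.99996).

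The unfolded protein response list, with chaperones of the endoplasmic reticulum, was called lower in camera with the preset correlation, but not with an estimated one. Of 18 unfolded protein response genes, 3 passed over all genes and 6 adjusted over the list alone, all lower, and 16 had an estimate below 0. Hspa5, the main chaperone of that compartment (BiP), fell from 4288 ± 249 to 2178 ± 114 CPM, Hsp90b1 (GRP94) from 2805 ± 108 to 1594 ± 53.5 CPM and Hyou1 from 459 ± 37.6 to 196 ± 34.4 CPM (SD, n = 3 per group). Manf went from 573 ± 106 to 269 ± 28.1 CPM (edgeR adjusted p = 0.0632). The list's median log2 fold change was -0.74 and its camera adjusted p was 1.9e-08, with an adjusted p of 0.139 with an estimated correlation and 0.0233 in directional fry.

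The lists of oxidative stress defence and of cholesterol synthesis were also called lower in camera with the preset correlation, but not with an estimated one. Directional fry called both lower, with an adjusted p of 0.0181 for each. Of 20 tested NRF2 targets, 2 passed over all genes and 4 adjusted over the list alone, all lower. Beside Txn1 these were the glutathione transferase Gsta4 (1232 ± 68.5 to 478 ± 121 CPM) and, over the list alone, the pentose phosphate enzymes Tkt (537 ± 25.9 to 321 ± 52.1 CPM) and G6pdx (378 ± 45.8 to 214 ± 15.6 CPM), with n = 3 per group. The median was -0.50 and the camera adjusted p was 3.8e-04, against an adjusted p of 0.139 with an estimated correlation. The limit given above for the chromosome 4 region of Rad23b and Txn1 applies to Txn1 here too. Without Txn1, a test chosen after seeing the data, camera gave an unadjusted p of 7.9e-04 for the other 19 members. Of 23 cholesterol synthesis genes 21 had an estimate below 0. None passed over all genes in edgeR, 3 had an unadjusted p under 0.05 and DESeq2 called 1, while 1 passed adjusted over the list alone, the squalene synthase Fdft1 (259 ± 59.0 to 109 ± 9.09 CPM). Lss, Nsdhl and Sc5d had log2 fold changes of -1.11 ± 0.42, -1.09 ± 0.47 and -0.94 ± 0.48 (SE). This list's median was -0.48 and its camera adjusted p was 3.8e-04, with an adjusted p of 0.146 with an estimated correlation.

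Matrix and TGF-beta genes stood higher as groups in camera, with exceptions among the collagens. Of 20 tested mesenchymal and matrix genes none passed over all genes in edgeR, 8 had an unadjusted p under 0.05 and DESeq2 called 7, while 6 higher and 2 lower passed adjusted over the list alone. Fibronectin (Fn1) went from 283 ± 42.6 to 578 ± 133 CPM, the lysyl oxidases Lox from 98.4 ± 45.3 to 297 ± 57.1 CPM and Loxl1 from 52.6 ± 39.6 to 190 ± 65.5 CPM, and biglycan (Bgn) from 200 ± 41.6 to 378 ± 64.1 CPM (SD, n = 3 per group). The 2 members that passed as lower were Col6a1 and Col1a1, the latter at 67.1 CPM in WT and 6.17 CPM in KO-labelled libraries. Of the 20 members, 6 had an estimate below 0. The median was 0.57 while the mean log2 CPM difference was -1.0e-04, and the camera adjusted p of 0.00151 became an adjusted p of 0.169 with an estimated correlation and 0.765 in directional fry. Of 24 TGF-beta pathway and target genes, 1 passed over all genes and 4 adjusted over the list alone, all higher. They included Inhba, the activin beta A subunit (0, 17 and 0 counts in WT, 2.83 ± 4.90 to 113 ± 18.4 CPM), Ltbp1, which binds latent TGF-beta (211 ± 69.4 to 426 ± 50.7 CPM), and Ccn2, the connective tissue growth factor (231 ± 89.1 to 463 ± 69.5 CPM). The log2 fold change of Inhba went from 5.24 to 11.03 without WT replicate 5. The camera adjusted p of 0.0387 became 0.201 with an estimated correlation, 0.114 in directional fry, 0.0914 without a filter on low counts, 0.0803 with a stricter one and 0.0506 with a prior count of 0.5. It was 0.0967 without WT replicate 6 and 0.0996, 0.167 and 0.129 without KO replicates 4, 5 and 6.

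The ligands themselves were not called or not tested. Tgfb2 stood at 27.4 ± 17.2 and 29.8 ± 23.2 CPM and Tgfb3 at 44.4 ± 41.7 and 32.2 ± 16.2 CPM (edgeR adjusted p = 0.99996 for each, n = 3 per group), with log2 intervals of -2.30 to 2.54 and -2.37 to 1.44 that leave large changes open. Tgfb1, too low to test, had 1 count in WT replicate 5, 2 counts in KO replicate 4 and 0 elsewhere. Gnrhr, the receptor for the hormone LHRH named in the study's title, and Cd274, the checkpoint ligand PD-L1, had no count in any library, which does not exclude a low level.

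Antigen presentation and epithelial genes included calls in each direction. B2m, the light chain of MHC class I, rose from 329 ± 52.4 to 908 ± 20.9 CPM (SD, n = 3 per group; edgeR adjusted p = 0.00407, 0.0683 at the highest when 1 library was left out). H2-D1, a heavy chain with close paralogs, went from 88.7 ± 29.3 to 224 ± 16.0 CPM (edgeR adjusted p = 0.192), and Calr, a chaperone of that pathway, from 3023 ± 305 to 1861 ± 284 CPM (edgeR adjusted p = 0.0742). Of 14 tested genes of the pathway 1 passed over all genes, and 2 higher and 1 lower adjusted over the list alone. The camera adjusted p of 0.0224 became 0.169 with an estimated correlation, 0.114 in directional fry, 0.119 without a filter on low counts and 0.0566 with only genes counted in all 6 libraries. It was 0.0718 and 0.0967 without WT replicates 5 and 6, and 0.0655, 0.167 and 0.0681 without KO replicates 4, 5 and 6. Of 12 ovarian surface and epithelial markers, Msln passed as higher and Krt19 (4202 ± 203 to 2223 ± 32.1 CPM) and Krt18 as lower, with Upk1b higher and Krt8 lower when adjusted over the list alone. This list had no common direction (camera adjusted p = 0.937).

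Mitosis genes stood slightly lower as a group in camera, and DNA replication genes were not called. Of 30 mitosis genes 26 had an estimate below 0, none passed in edgeR over all genes or adjusted over the list alone, 2 had an unadjusted p under 0.05 and DESeq2 called 0. Aurka went from 147 ± 12.8 to 69.9 ± 12.9 CPM and Top2a from 2027 ± 211 to 1648 ± 120 CPM (SD, n = 3 per group). The median was -0.23, and the camera adjusted p was 0.0196. It became 0.169 with an estimated correlation, 0.0806 with library totals and 0.144 after correction for GC content and length. Without WT replicate 6 it was 0.0967 and without KO replicate 4 it was 0.0655. Directional fry called the list lower, with an adjusted p of 0.0233. Histone genes expressed in S phase had a median of -0.59 over 22 members and a camera adjusted p of 0.00538, with an adjusted p of 0.154 with an estimated correlation and 0.114 in directional fry. Hist1h1a went from 373 ± 82.8 to 162 ± 77.3 CPM. These transcripts mostly lack a poly(A) tail and belong to a family of near-identical copies, so their level also depends on the selection of poly(A) RNA and on how shared reads were counted. The DNA replication list had a camera adjusted p of 0.239 and a median of -0.21, with an adjusted p of 5.1e-05 in mixed fry.

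**Figure D2:**
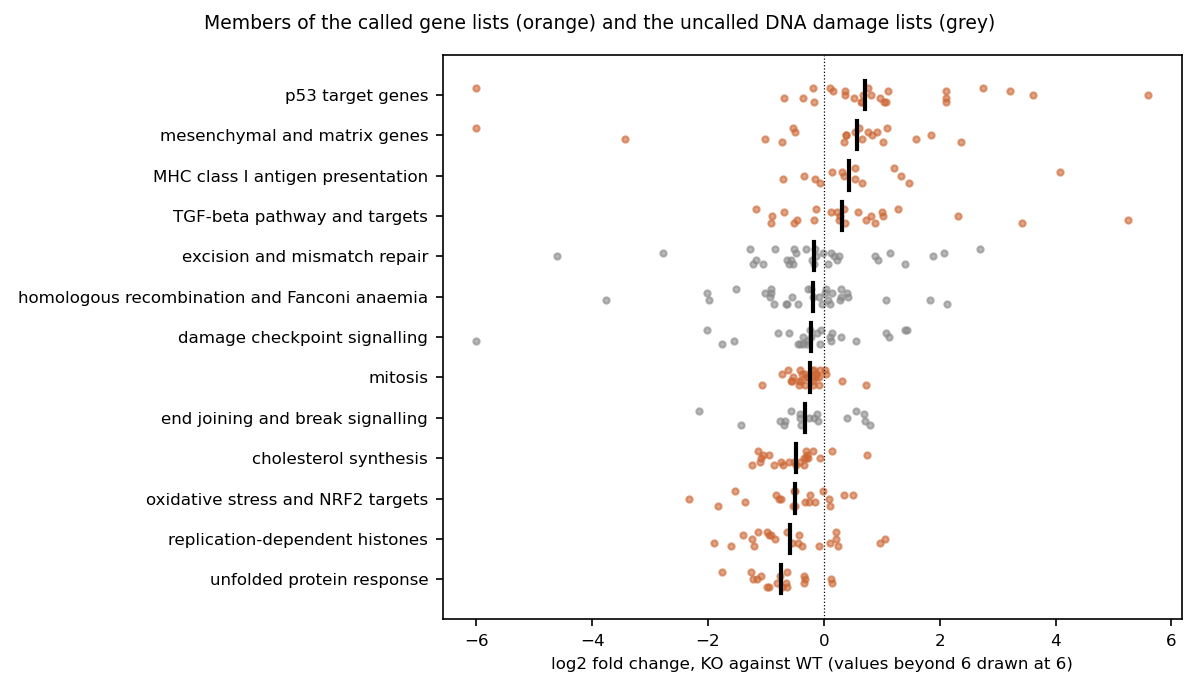
The log2 fold changes, KO-labelled against WT, of the tested members of the 9 gene lists called by camera (orange) and the 4 DNA damage lists not called (grey), with a black bar at each list's median. The medians run from -0.74 for the unfolded protein response to 0.71 for p53 target genes.

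The remaining lists were not called by camera. The adjusted p was 0.0998 for RNA modification enzymes (median log2 fold change -0.44) and 0.0998 for the type I interferon response (0.79), and the latter was under 0.05 in 6 other settings that test a direction, 0.0177 without a filter on low counts among them. RNA modification enzymes were lower without that filter (0.0350). It was 0.108 for amino acid and ATF4 response genes (-0.39), 0.108 for glycolysis and hypoxia (-0.24), 0.310 for platinum transport and binding (-0.18), 0.329 for oxidative phosphorylation (-0.15) and 0.588 for ribosome biogenesis (-0.13). The ATF4 list was lower with only genes counted in all 6 libraries (0.00825) and in cameraPR (0.0294), and the glycolysis list without WT replicate 4 (0.0350) and in cameraPR (0.0497). Cytosolic ribosomal proteins (adjusted p = 0.604, median 0.03, mean -0.05) and chemokines and NF-kB targets (0.937, median -0.20, tested direction up) had medians, means or tests that differed in sign. Within the ATF4 list, Ddit4, Asns and Atf4 passed as lower when adjusted over the list alone, with log2 fold changes of -2.47 ± 0.50, -1.41 ± 0.30 and -1.09 ± 0.26 (SE). Ptgs2, the inducible cyclooxygenase, passed as higher when adjusted over the chemokine list alone (170 to 460 CPM).

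Markers of other cell types were nearly absent, apart from Esam and Dcn. Of the immune, endothelial and stromal lists only 1 gene each entered the test. Esam had 65, 163 and 75 counts in WT and 0, 0 and 2 in KO-labelled libraries, and the stromal gene Dcn stood at 700.2 CPM in WT and 1117 CPM in KO-labelled libraries (edgeR adjusted p = 0.0693 and 0.246). Whether ID8 cells are the source of the Dcn reads was not tested. KO replicate 6 had counts of 8 immune, 7 endothelial and 9 stromal markers, against at most 2 of any of these lists in the other libraries. Ribosomal RNA genes took 24.5% ± 2.94 of counts in WT and 19.8% ± 1.73 in KO-labelled libraries (SD, n = 3 per group; exact permutation p = 0.2). Mitochondrially encoded mRNAs (camera adjusted p = 0.937, median -0.13, mean 0.06) and immediate early and heat shock genes (0.570, median 0.17) were not called.

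**Figure D3:**
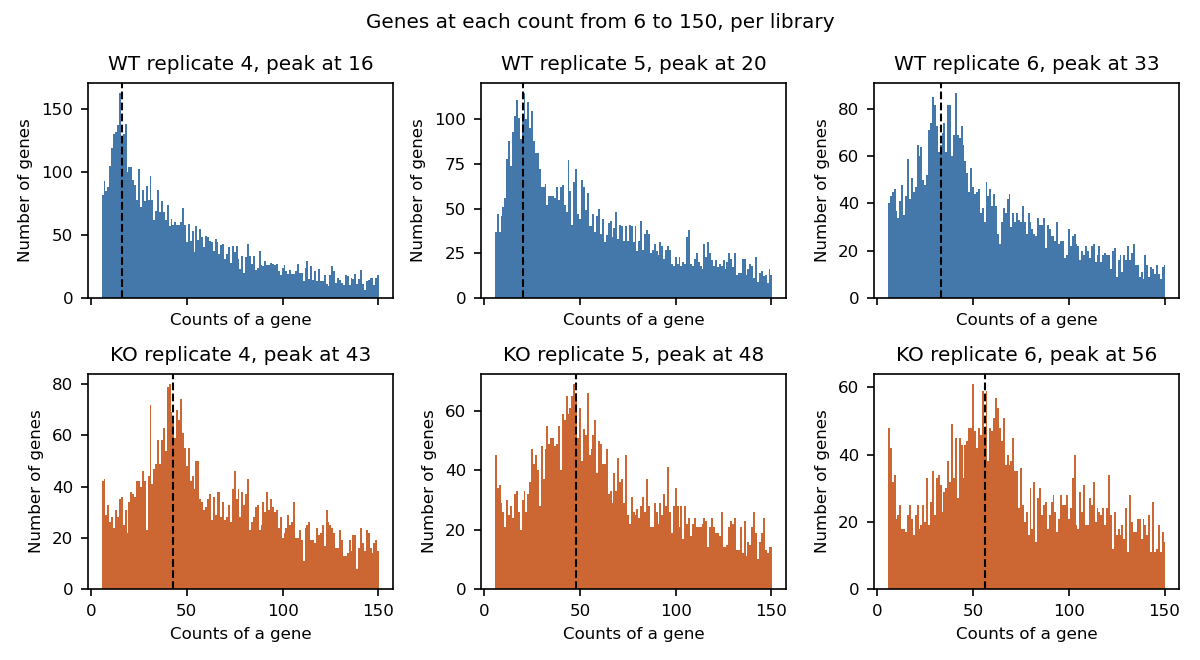
Number of genes at each count from 6 to 150, with 1 panel per library and a dashed line at the peak. The peaks lie at 16, 20 and 33 counts in WT replicates 4, 5 and 6 (blue) and at 43, 48 and 56 counts in KO replicates 4, 5 and 6 (orange).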

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

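The setting moved how many genes were called. Of the 33, 23 kept their call under each planned setting run on all libraries, apart from the threshold of 0.01 and the test against a log2 fold change of 1. The count of genes past the threshold was 33 and became 234 with DESeq2, 91 without a filter on low counts, 16 at a threshold of 0.01 and 105 (41 higher, 64 lower) when counts were divided by the histogram peak, a setting chosen after seeing the data, and all 33 were among the 234, the 91 and the 105. The count at least 2-fold changed was 28 and became 178, 73 and 86 in those settings, and 5 in a test against a log2 fold change of 1. Leaving out 1 library gave 6 to 29 genes and 6 to 25 at least 2-fold changed, with fewer samples in each fit. Of the 33 calls, 10 were lost without WT replicate 4, 28 without WT replicate 5, 27 without WT replicate 6, and 18, 15 and 17 without KO replicates 4, 5 and 6. The log2 fold change of Nat10, -0.07, was 0.0195 with limma-voom, 0.0265 with library totals, 0.0307 after thinning and 0.0595 when counts were divided by the histogram peak, and ran from -0.35 to 0.35 with 1 library left out. The cause was not tested, and each lies within the interval around the value. Library totals moved the median log2 fold change of all genes from -0.02 to 0.09.

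Of the 9 lists called by camera, 0 were called with an estimated correlation, with adjusted p-values from 0.139 to 0.265. That setting also missed the shifted unfolded protein response list in every simulation. Genes there were independent, so its performance on correlated lists was not tested. Among the called lists, MHC class I, NRF2, mitosis, histones and TGF-beta had an estimated correlation under the preset 0.01. An estimate above the preset therefore does not account for the calls lost in those lists. Directional fry called 5 lists, all lower, 4 of them among the 9. The other settings that test a direction called 7 to 11 lists. The lists of the unfolded protein response, NRF2 targets and cholesterol synthesis lost their call in no other setting. The numbers shared by WT and KO replicates did not pair the libraries: same-numbered deviations correlated at -0.02, 0.00 and -0.01, and 0 of 3 libraries correlated best with their own number. With the replicate block 38 genes passed, 34 of them at least 2-fold, 28 of the 33 calls were kept, Nat10 stood at -0.06 and 9 lists were called. The calls lie mostly among abundant genes, and the median coefficient of biological variation was 1.84 in the least abundant decile of genes and 0.303 in the most abundant.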

Other observations

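The tests of YAP targets, of the count histograms, of Nat10 and of the other splits for genes and lists were chosen after the results that prompted them were seen.

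A set of YAP and TEAD target genes, which respond to cell stretch and adhesion, stood higher in the KO-labelled libraries. A literature list of 22 was written after the gene tests, prompted by the rise of Ankrd1, so it is no independent test. Without Ankrd1, 14 of 16 tested members had an estimate above 0, the median was 0.58 and none passed over all genes. Camera gave an unadjusted p of 5.9e-05, or an unadjusted p of 0.0357 with an estimated correlation. These cannot be set beside the adjusted p-values of the fixed lists. Camera with an estimated correlation gave the NRF2 list an unadjusted p of 0.0107, or 0.0218 without Txn1. Ccn2 (231 ± 89.1 to 463 ± 69.5 CPM), Crim1 (312 ± 32.9 to 511 ± 56.5 CPM), Ptpn14 (94.2 ± 17.9 to 197 ± 42.2 CPM) and Ccn1 (49.9 ± 19.4 to 121 ± 34.6 CPM) were higher in every KO-labelled library than in any WT library (SD, n = 3 per group). The cause was not tested, and 4 of the members also stand in the lists described above.

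The number of genes at each count did not fall smoothly. After a low point at 6 to 13 counts it rose to a peak at 16, 20 and 33 counts in WT replicates 4, 5 and 6 and at 43, 48 and 56 counts in KO replicates 4, 5 and 6. The mean peak was 23 ± 8.89 against 49 ± 6.56 counts (SD, n = 3 per group; exact permutation p = 0.1, the smallest possible). Among genes whose level in the other 5 libraries predicted 1 to 2 such peaks, 24.6%, 28.3% and 26.6% in WT and 19.3%, 16.3% and 18.7% in KO-labelled libraries had 5 counts or fewer. A Poisson law in units of the peak gave 23.9% to 24.6%, and a Poisson law in reads gave at most 0.0131%. At 4 to 8 peaks the observed shares were 2.23, 3.27 and 0.990 times the peak law in WT and 1.42, 1.06 and 0.424 times in KO-labelled libraries, so that law holds only roughly.

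Genes at 0 in 1 library and at 50 or more counts in both others of its group were the clearest sign of this, with 560 gene and library pairs. Sequencing depth is argued against, because reads at the level of the other libraries would give 5.0e-18 such pairs by Poisson counting. Few captured molecules per gene stay open. The counts per molecule estimated from the variance were 1.71 times those estimated from the zeros, within the 2-fold asked for beforehand, but both estimates come from the same counts and zeros raise the variance, and the peak law missed at 4 to 8 peaks. The KO-labelled libraries held 4.09 times as many of these pairs as WT (450 against 110; 165, 195 and 90 in KO replicates 4, 5 and 6 and 15, 11 and 84 in WT replicates 4, 5 and 6). WT replicate 6 thus held most of the WT pairs, about as many as KO replicate 6. The ratio meets the 3-fold condition written beforehand for an effect of the knockout. The verdict was nevertheless set to undecided after the values were seen, because 50 counts are about 1 peak in the KO-labelled libraries and more than 1 in every WT library. Among genes at 1 to 2 peaks the KO-labelled libraries had fewer low values than the Poisson law gave (ratios 0.790, 0.665 and 0.758), and at 2 to 4 peaks as well (0.854, 0.579 and 0.688, against 1.12, 1.52 and 1.19 in WT), but not at 4 to 8 peaks in replicates 4 and 5. The counts per molecule differed less than the peaks, at 17.7 in WT and 21.3 in KO-labelled libraries from the zeros and 29.9 and 36.9 from the variance. An effect of the knockout, another difference between the lines and a lower capture are therefore all left open.

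Nat10 mRNA was the same in libraries labelled WT and KO within its error. An exchange of a WT library for a KO library is argued against by the gene counts alone. Each of the 9 splits with 1 pair exchanged called 0 genes by edgeR where the labelled split called 33. They had at most 225 at an unadjusted p under 0.05, and at most 19 by DESeq2. Correlations between libraries did not set the KO-labelled ones apart. They were 0.571 to 0.602 within KO, 0.623 to 0.705 within WT and 0.543 to 0.630 between the groups. The histogram peaks also followed the labels, so the split counts do not show that the guide set the labelled split apart. A fall of Nat10 mRNA too small for the precision stays open, since the lower bound of its interval was -1.09 on the log2 scale. Edits that change the protein and leave the mRNA also stay open, with KO-labelled Nat10 at 94.9% of the WT mean, because gene counts hold no sequence at the cut site. A control line labelled KO as a whole group was not tested.

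The fall of the unfolded protein response list was tested against 3 technical sources. After correction for GC content and exon length its median log2 CPM difference was -0.70 (interquartile range -0.999 to -0.36) against -0.88 (-1.16 to -0.58) before, and its camera adjusted p was 4.3e-06. A difference in total reads alone is argued against, with an adjusted p of 2.0e-08 after every library was thinned to the smallest total, which leaves differences in capture as they were. No 1 library accounts for it, with an adjusted p of at most 3.0e-05 when any library was left out. None of these tests addresses RNA selection or capture, and signs of those differed between the groups too: histones were lower (median -0.59), the share of Gm42418 was lower and the histogram peak was higher. The cause is left open, and the call was lost with an estimated correlation (adjusted p = 0.139).

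With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The labelled split called 33 genes, 28 at least 2-fold, and 9 lists, and held 4 genes at 0 in all libraries of 1 group and at 50 or more counts in all of the other. The highest of the other splits were 0 genes, 0 at least 2-fold, 3 lists and 3 such genes, and 1 of the 10 splits, the labelled one, reached each real value. With counts divided by the histogram peak the labelled split called 105 genes and the highest other 2, and with DESeq2 it called 234 and the highest other 19.

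KO replicate 6 carried traces of genes of other cell types. C1qc, C1qb, Csf1r, Kdr, Pecam1, Lum, Pi16 and Pdgfrb had 2 or 3 counts there and 0 in the other 5 libraries, far under its peak of 56 counts. It also had 1604 genes at 1 to 5 counts, against 906 to 1088 in the others.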
